A study of Mus musculus with 18 samples.

How the data were processed

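Bone marrow cells of 18 mice were flash-frozen, total RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised to Affymetrix arrays with probesets at the 3' end of transcripts, per the labels' protocols. The authors deposited a table of log2 expression values for 45101 probesets on 18 arrays, normalized between arrays with RMA (background correction, quantile normalization and a summary per probeset), per the submitters' processing notes. The version of RMA, the software and the probe definition file are not given in the sources used here. The log2 scale was taken from the deposited values, which run from 1.56 to 14.2. Array medians were 4.27 to 4.40 and interquartile ranges 2.90 to 3.36, correlations between arrays were 0.930 to 0.995, and no pair of arrays held identical values. Arrays give no read depth, so the number of arrays limits the precision.

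Groups were taken from the labels: WT (4 mice), CCAT2-G and CCAT2-T (4 each, together the 8 DRAI- mice) and CCAT2-GT (6 DRAI+ mice). The titles call all samples biological replicates. The replicate numbers were taken from the titles and do not mark a shared animal, litter or day in the labels, so they were not used as pairs. The letter in each mouse identifier, G or T also within the CCAT2-GT group, is not explained by the labels and served only as a covariate in an alternative.

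Probesets were named through the platform annotation: 34958 had 1 gene symbol, 932 had several and 9211 had none listed, and only the first kind was used for genes. Of the resulting 18194 genes, 9012 had more than 1 probeset and were represented by the brightest. Genes whose mean lay below the 30th percentile of all probeset means (3.30) were left out, which kept 14505. Beside a named gene the direction of its other probesets was recorded.

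Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on all 18 arrays, with 3 groups for WT, DRAI- and DRAI+ and 4 groups for the alleles, and p-values were adjusted with Benjamini and Hochberg's method over all genes, with a threshold of 0.05. All differences are log2 values of the first group named minus the second, and errors are SE from the fit or SD between mice. Lists of marker and pathway genes were fixed before the data were examined: 32 lists with 1046 entries, of which 900 matched a gene and 876 were measured. The 31 lists other than the sex-linked one were tested with limma's camera, two-sided, at its preset correlation of 0.01 and adjusted over the 31 lists. Camera compares a list with all other genes and treats its members as nearly independent, so the test was repeated with an estimated correlation, with fry, which tests whether the genes of a list move one way on balance, and with an exact permutation test of each mouse's list score. With the estimated correlation, fry and the adjusted permutation test, 0 lists passed in each of the 3 comparisons. Some lists share genes, for example 3 between plasma cells and the unfolded protein response and 2 between B-cell precursors and dendritic cells. For members of a list, p-values were also adjusted over the list alone.

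The genes named were chosen by a rule fixed before the data were examined. It takes the genes of largest change among those past the threshold or, where none passed, the 5 with the smallest p in each direction (3 for the alleles), without predicted genes and immunoglobulin or T-cell receptor segments. It adds 2 to 4 members of smallest p for each list described, and Ezh2, Myc, Pvt1, Adar and 15 lineage markers whatever their values, of which Hbb-bt was not measured. For some lists fewer members than that are printed below, and for some none. A further gene of that rule is not reported here.

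Alternatives fixed beforehand were median centring and quantile normalization on top of the deposited values, no filter or a filter at the 50th percentile, the mean of a gene's probesets, every probeset tested, eBayes without trend or with robust estimation, array weights, a fit of the compared groups alone, 4 groups in the model, a minimum fold of 1.5, the replicate number as a block, the identifier letter and a sex score (Xist minus Y-linked genes) as covariates, and leaving out each mouse in turn. Alternatives chosen after seeing the data left out the 3 stroma-rich, 5 narrow or 4 Xist-high arrays, used the immediate-early score, stroma score or interquartile range as a covariate, or treated the 5 narrow arrays as a block. No labels name a hybridisation batch, so this set is not a recorded one.

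The procedure was tested on simulated data with 200 of 14505 genes, picked at random, changed. Values were drawn for each gene on its own from a normal distribution with that gene's spread within the 4 groups. They hold no correlation between genes and none of the differences between arrays described below. The shares that follow are therefore not the power in the real data, where Cd79a differed by -2.32 between DRAI+ and DRAI- mice without passing. For DRAI+ against WT it recovered 50.7% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold, and for DRAI+ against DRAI- 61.2%, 95.5% and 100%. The corresponding shares were 53.7%, 85.1% and 97.0% for DRAI- against WT and 35.8%, 85.1% and 97.0% for CCAT2-G against CCAT2-T. Against WT they were 37.3%, 79.1% and 95.5% for CCAT2-G and 35.8%, 83.6% and 98.5% for CCAT2-T. False calls numbered 1 to 11 per comparison. Raw scanner files were not used here.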

Results

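Total RNA from the bone marrow of 18 mice on a C57Bl6 background was measured on Affymetrix arrays, 1 array per mouse, each labelled as a biological replicate. The mice were 4 wild-type (WT) animals, 4 that overexpressed the G allele of the long non-coding RNA CCAT2 in all tissues, 4 that overexpressed its T allele and 6 labelled CCAT2-GT. The labels give the CCAT2-G and CCAT2-T mice together, 8 animals, as DRAI- and the 6 CCAT2-GT mice as DRAI+, a status that they do not spell out. The series title places the work in myeloid malignancy, so the comparisons ask how marrow expression differs between WT, DRAI- and DRAI+ mice and between the alleles. Array medians lay between 4.27 and 4.40 on the log2 scale, and the number of arrays limits the precision of every value below.

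The arrays differed in ways that the groups do not name. The interquartile range was 2.90 to 3.07 on 5 arrays (WT replicates 1 and 2, CCAT2-G replicate 1, CCAT2-T replicates 1 and 2) and at least 3.15 on the others. None of the 5 came from a DRAI+ mouse. The list of marrow stroma, bone and endothelial genes was highest in WT replicate 4 and CCAT2-GT replicates 4 and 6, at 6.93, 6.96 and 7.68, with the next mouse at 6.51. Xist, the RNA that silences an X chromosome in female cells, was above 10.7 in CCAT2-T replicate 3 and CCAT2-GT replicates 2, 3 and 5 and at most 4.05 in the rest. That makes 0 of 4 WT, 1 of 8 DRAI- and 3 of 6 DRAI+ mice with high Xist. The Y-linked gene Eif2s3y was at 2.14 to 2.32 in the Xist-high mice and at 6.96 or more in the rest. By these genes the Xist-high mice were female and the rest, all WT mice included, male. Values among the 13 arrays of wider spread, values with the 5 narrow arrays as a block and values without the stroma-rich or Xist-high arrays are alternatives chosen after seeing the data. Among the 13 wider arrays WT replicates 3 and 4, both flagged below as standing apart, are the only WT mice. Within the 5 narrow arrays WT replicates 1 and 2 are set against CCAT2-G replicate 1 and CCAT2-T replicates 1 and 2. A list said to rise, fall or shift as a group was called by camera with its preset correlation, which treats genes as nearly independent. No list passed the exact permutation test of each mouse's score after adjustment. Before it, the smallest p of that test was 0.081 in DRAI+ against WT, 0.141 in DRAI- against WT and 0.0163 in DRAI+ against DRAI-.

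By camera, interferon genes and genes of the unfolded protein and integrated stress response rose as groups in DRAI+ marrow against WT. In the exact permutation test of mouse scores, unadjusted p was 0.138 for the interferon list and 0.081 for the stress list. Of the 39 measured genes of the type I interferon response, 36 were higher, with a mean log2 difference of 0.43 (camera, adjusted p = 7.66e-18, but adjusted p = 0.464 with an estimated correlation). Oas1a, which makes the activator of the antiviral RNase L, was at 8.23 ± 0.65 (SD, n = 6) in DRAI+ and 7.00 ± 0.54 (SD, n = 4) in WT mice. Among other members, Rtp4 was higher by 1.02 (SE 0.38), Slfn5 by 0.92 (SE 0.30) and Ifi204, which binds foreign DNA, by 0.86 (SE 0.26). Of the 30 genes of the unfolded protein and integrated stress response, 27 were higher, by 0.28 on average (adjusted p = 1.28e-10, and adjusted p = 0.464 with an estimated correlation). All 6 DRAI+ mice lay above the WT mean. Xbp1, the transcription factor of that response, was higher by 0.50 (SE 0.17). The disulfide isomerases Pdia4 and Pdia6 were higher by 0.53 (SE 0.19) and 0.46 (SE 0.18), and Edem1, which sends misfolded glycoproteins to degradation, by 0.52 (SE 0.20). Xbp1 and Edem1 are also on the plasma cell list, which differed by 0.08 without passing (camera, adjusted p = 0.0812). Whether the stress shift is separate from plasma cells was not tested. Among the 13 arrays of wider spread the interferon list differed by 0.63 and the stress list by 0.16. With the narrow arrays as a block the values were 0.44 and 0.11. Without CCAT2-GT replicate 2 the stress list differed by 0.18. Interferon scores were 6.78, 7.62 and 7.23 in the Xist-high CCAT2-GT replicates 2, 3 and 5 and 6.90, 7.56 and 6.51 in replicates 1, 4 and 6. In the same order stress scores were 8.42, 7.67 and 7.80 and 7.83, 7.75 and 7.80. WT means, from mice without high Xist, were 6.67 for interferon and 7.59 for stress.

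Mature B-cell and B-cell precursor genes fell as groups by camera in DRAI+ marrow against WT. Unadjusted p in the exact permutation test of mouse scores was 0.148 for mature B cells and 0.110 for the precursors. Of 27 mature B-cell genes 26 were lower, with a mean of -0.76 (adjusted p = 1.75e-13, and adjusted p = 0.510 with an estimated correlation). Of 25 B-cell precursor genes 23 were lower, with a mean of -0.85 (adjusted p = 6.54e-12, and adjusted p = 0.510 with an estimated correlation). Ms4a1, which encodes the surface antigen CD20, differed by -1.58 (SE 0.66), the lymphotoxin subunit Ltb by -0.79 (SE 0.32), and Spib by -1.44 (SE 0.68). The B-cell transcription factor Bach2 differed by -1.64 (SE 0.75), and Cd79b, a signalling chain of the B-cell receptor, by -1.14 (SE 0.52). WT mice differed among themselves. WT replicates 1 and 2, both narrow arrays, had mature B-cell scores of 8.64 and 8.50 and WT replicates 3 and 4 had 7.50 and 6.89. Among the 13 arrays of wider spread both calls ended, with differences of -0.07 for mature B cells and -0.26 for the precursors. There WT replicates 3 and 4 were the only WT mice. With the narrow arrays as a block the mature B-cell call also ended (-0.30), while the precursor list kept its call at -0.43. Without WT replicate 1 the mature B-cell list differed by -0.50.

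Erythroid, monocyte and megakaryocyte genes also shifted as groups by camera. The exact permutation test of mouse scores gave unadjusted p = 0.171, 0.395 and 0.610 for them in DRAI+ against WT. Of 34 erythroid genes 33 were lower in DRAI+ than in WT mice (mean -0.25, adjusted p = 4.06e-07, and adjusted p = 0.554 with an estimated correlation). They include the water channel Aqp1 at -0.47 (SE 0.26) and the anion exchanger Slc4a1 at -0.28 (SE 0.16). That list differed by -0.29 among the wider arrays, by -0.14 without passing with the block, and by -0.16 without CCAT2-GT replicate 4. Monocyte and macrophage genes rose (23 of 31 higher, mean 0.29, adjusted p = 0.000314, and adjusted p = 0.554 with an estimated correlation). The members of smallest p were the high-affinity Fc receptor Fcgr1 at 0.93 (SE 0.33), the lectin Clec4a3 at 0.73 (SE 0.33), Ctss at 0.27 (SE 0.15) and Ms4a6d at 1.07 (SE 0.58). The monocyte call ended among the wider arrays (0.15), with the block (0.12) and without CCAT2-GT replicate 6 (0.11). The value was 0.18 without WT replicate 3 and 0.49 without WT replicate 4. Megakaryocyte and platelet genes rose by 0.43 (24 of 26 higher, adjusted p = 0.000511, and adjusted p = 0.757 with an estimated correlation). Among them were the adhesive protein Thbs1 at 0.95 (SE 0.60) and the platelet selectin Selp at 0.89 (SE 0.58), but only 3 of 6 DRAI+ mice lay above the WT mean. Without the 3 stroma-rich arrays their direction turned (-0.16). Among the wider arrays and with the block the call ended (0.14 and 0.26), as it did without CCAT2-GT replicate 4 (0.04) or 6 (0.08). The megakaryocyte value was 0.28 without WT replicate 3, 0.77 without WT replicate 4 and 0.76 without CCAT2-GT replicate 1. Without the 4 Xist-high arrays the lists differed by -0.37 (erythroid), 0.48 (monocytes) and 1.11 (megakaryocytes).

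In DRAI+ against WT 7 more lists passed, and each lost its call with an estimated correlation (adjusted p = 0.554 to 0.880 with an estimated correlation). Eosinophil, basophil and mast cell genes rose by 0.27 (21 of 23 higher, adjusted p = 0.00244), with the histamine-forming enzyme Hdc at 0.63 (SE 0.32) and the eotaxin receptor Ccr3 at 0.78 (SE 0.53). MYC targets and ribosome biogenesis genes rose by 0.13 (33 of 38, adjusted p = 0.00012), for example Nop16 at 0.40 (SE 0.21) and the spermidine synthase Srm at 0.39 (SE 0.24). Granulocyte-monocyte precursor genes rose by 0.12 (15 of 20, adjusted p = 0.0195), and genes of mitochondrial respiration rose by 0.06 (31 of 36, adjusted p = 0.0324), with the cytochrome c oxidase subunit Cox5a at 0.21 (SE 0.12). Skeletal muscle genes fell by 0.35 (18 of 20 lower, adjusted p = 6.94e-06), with the muscle enolase Eno3 at -0.53 (SE 0.21) and Myoz1 at -0.37 (SE 0.19). DNA repair genes fell by 0.08 (29 of 37, adjusted p = 0.0168) with the end-joining ligase Lig4 at -0.54 (SE 0.22). Cell cycle genes fell by 0.08 (36 of 43, adjusted p = 0.0126) with Nusap1 at -0.29 (SE 0.16) and the replication licensing factor Cdt1 at -0.18 (SE 0.12). Among the wider arrays and with the block, the respective differences were 0.15 and 0.21 for eosinophils, basophils and mast cells, 0.06 and -0.03 for MYC targets, and -0.01 and -0.07 for the precursors. They were -0.08 and -0.10 for respiration, -0.58 and -0.24 for muscle, -0.18 and -0.17 for DNA repair and -0.29 and -0.22 for the cell cycle. The calls of eosinophils, basophils and mast cells, of MYC targets and of the precursors ended in both settings, respiration turned in both, and the muscle call ended with the block. Single mice ended several of these calls: WT replicate 4 for muscle (-0.02 without it), the cell cycle (0.03) and DNA repair (-0.03). WT replicate 3 and CCAT2-GT replicate 3 did so for the cell cycle (-0.05 and -0.02) and DNA repair (-0.07 and -0.05), and CCAT2-GT replicate 5 for eosinophils, basophils and mast cells (0.10). The precursor call ended without WT replicate 1 (0.06) or 2 (0.10) and without CCAT2-GT replicate 1 (0.07), 2 (0.10) or 4 (0.06). The value was 0.20 without CCAT2-GT replicate 3. The respiration call ended without WT replicate 1 (0.00339), 2 (0.02) or 3 (0.06) and without CCAT2-GT replicate 2 (0.03) or 6 (0.00959). The value was 0.16 without WT replicate 4 and 0.10 without CCAT2-GT replicate 1 or 3. Without the 4 Xist-high arrays the call of eosinophils, basophils and mast cells ended (0.07). Without the 3 stroma-rich ones those of muscle (-0.03), the cell cycle (0.03) and DNA repair (-0.01) ended. The cell cycle value lay at -0.15 without WT replicate 1 or 2 and at -0.14 without CCAT2-GT replicate 2. With array weights the DNA repair call ended (-0.02), the cell cycle turned (0.06), and the values were 0.62 for eosinophils, basophils and mast cells, 0.12 for respiration and -0.17 for muscle. The respiration call also ended with median centring (0.06), quantile normalization (0.04), the replicate block (0.02) and the stroma score as a covariate (0.06), and the cell cycle call with the mean of a gene's probesets (-0.05). Without the 4 Xist-high arrays the precursor and respiration values were 0.26 and 0.09.

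The other 17 lists did not pass in DRAI+ against WT. Genes of myeloid malignancy drivers in signalling and transcription differed by 0.12 (adjusted p = 0.0551), plasma cells by 0.08 (adjusted p = 0.0812), mature neutrophils by 0.14 (adjusted p = 0.150) and Polycomb and chromatin regulators by -0.03 (adjusted p = 0.259). Adjusted p was 0.307 each for p53 targets, at -0.04, inflammatory genes of the NF-kB pathway, at 0.14, and RNA editing and modification genes, at 0.04. Values for neutrophil secondary and tertiary granules (-0.08), marrow stroma (-0.00302), WNT targets (0.00797), the spliceosome (-0.02), stem and progenitor cells (0.07), ribosomal proteins (0.01), immediate-early genes (0.10), T and NK cells (-0.00437), replication-dependent histones (0.02) and dendritic cells (-0.11) had adjusted p of 0.328 to 0.918. The mean and camera's direction, which rests on moderated t-statistics set against those of all other genes, were opposite for 4 of the lists that did not pass. These were stroma, immediate-early genes, T and NK cells and histones. The mean and median were opposite for 3.

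No single gene passed in DRAI+ against WT with limma (0 of 14505, smallest adjusted p = 1.00). In all, 382 genes had an unadjusted p under 0.05, 171 higher and 211 lower, where 725 would by chance. No gene of the lists passed when adjusted over the list alone either. Of the B-cell genes, however, 18 mature ones did so without WT replicate 4, 16 mature ones with the interquartile range as a covariate, and 23 mature and 20 precursor genes with array weights. The smallest p-values belonged to Parp12 at 0.76 (SE 0.20), Sema4g at 0.41 (SE 0.11), Oas1a at 1.23 (SE 0.35), Zfyve9 at 0.43 (SE 0.12) and Pde7b at 0.82 (SE 0.23) among higher genes. Among lower ones they belonged to Manea at -0.43 (SE 0.11), Sox6os at -0.44 (SE 0.12), Rmnd5a at -0.46 (SE 0.13), Nek3 at -0.47 (SE 0.14) and Serinc5 at -0.68 (SE 0.21). Ezh2, the methyltransferase of Polycomb complex PRC2, differed by -0.18 (SE 0.13), the proto-oncogene Myc by 0.21 (SE 0.22), its neighbour Pvt1 by 0.08 (SE 0.24) and the RNA-editing enzyme Adar by 0.17 (SE 0.14). Lineage markers did not pass either, including the granule enzymes Mpo (0.24, SE 0.25) and Elane (-0.09, SE 0.34), Ltf (-0.04, SE 0.21), and S100a8 (-0.03, SE 0.06). The same holds for Csf1r (0.32, SE 0.22), Klf1 (-0.30, SE 0.24), Cd3e (-0.01, SE 0.21), Kit (0.06, SE 0.25) and Cd34 (0.30, SE 0.38). Gata1, at 8.76 in both groups, Pf4 (0.12, SE 0.74), Cd79a (-1.62, SE 0.78) and Vpreb1 (-1.46, SE 0.88) were among them, and Hbb-bt was not measured. For Kit and Nusap1, 1 of 2 probesets pointed the other way. With array weights, an alternative that gives WT replicate 2 a weight of 4.50 and WT replicate 4 one of 0.385, 456 genes passed, 137 higher and 319 lower.

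**Figure D1:**
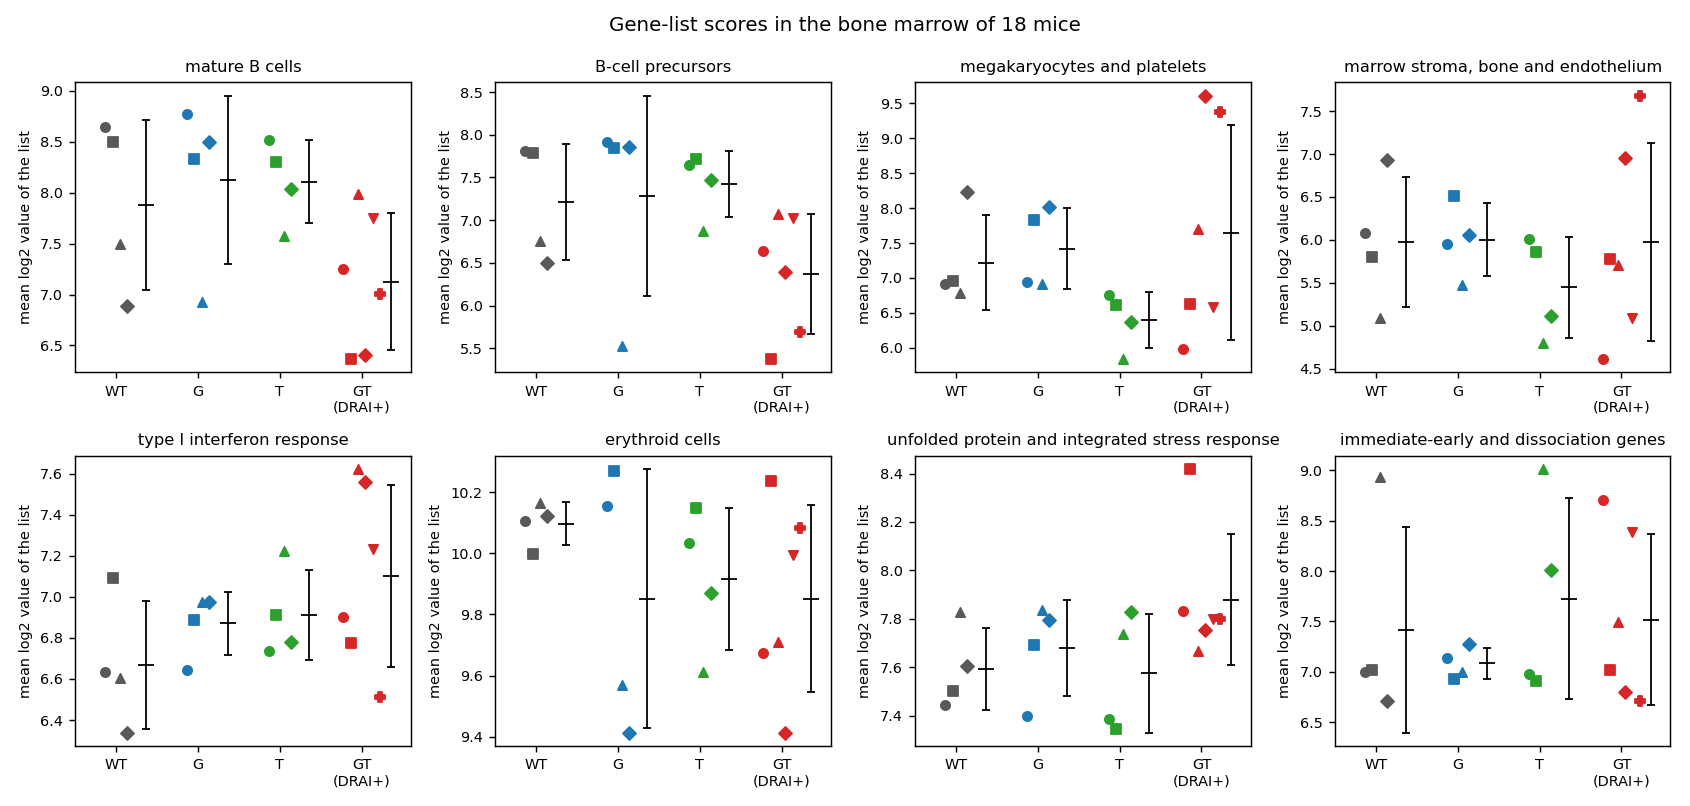
Mean log2 value of the genes of 8 lists in each mouse, by group (WT, CCAT2-G, CCAT2-T and CCAT2-GT), with 1 point per mouse, a marker for each replicate number and a bar for the mean ± SD of the group. All 6 CCAT2-GT mice lie below the DRAI- mean of 8.12 in the mature B-cell panel, and WT mice span 6.89 to 8.64 there.

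Camera's smallest p-values in DRAI- against WT belonged to erythroid and cell cycle genes, which fell, and interferon genes, which rose, as groups. Of 34 erythroid genes 33 were lower, with a mean of -0.21 (camera, adjusted p = 1.15e-07, and adjusted p = 0.830 with an estimated correlation), for example the carbonic anhydrase Car1 at -0.53 (SE 0.33) and the red cell adducin Add2 at -0.34 (SE 0.22). Of 43 cell cycle genes 40 were lower, with a mean of -0.12 (adjusted p = 6.14e-06, and adjusted p = 0.830 with an estimated correlation), among them the cyclin Ccnb2 at -0.27 (SE 0.17) and the ubiquitin-conjugating enzyme Ube2c at -0.19 (SE 0.13). Of 39 interferon genes 32 were higher, by 0.22 on average (adjusted p = 1.93e-05, and adjusted p = 0.830 with an estimated correlation), with Oas2 at 0.72 (SE 0.33), Trim30a at 0.46 (SE 0.23) and Ifi35 at 0.31 (SE 0.15). Within the 5 narrow arrays the erythroid list differed by 0.06 and the interferon list, without passing, by -0.10, both opposite to the value over all arrays, and the cell cycle call ended (-0.04). The same lists differed by -0.40, 0.50 and -0.26 among the 13 wider arrays and by -0.19, 0.23 and -0.16 with the block. Without WT replicate 4 the cell cycle call ended (-0.01) and the interferon value was 0.12, which was 0.37 without WT replicate 2. The cell cycle value was -0.19 without WT replicate 1 and -0.20 without WT replicate 2. With array weights the erythroid call ended (-0.08) and the cell cycle (0.04) and interferon genes (-0.02) turned, and the cell cycle call ended with the interquartile range as a covariate (-0.05).

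T and NK cell, mature B-cell and dendritic cell genes rose, and megakaryocyte and secondary and tertiary granule genes fell, in DRAI- against WT. Each of these calls was lost at adjusted p = 0.830 with an estimated correlation. B-cell precursors (0.14, adjusted p = 0.184), plasma cells (-0.07, adjusted p = 0.502) and the list of granulocyte-monocyte precursors and primary granules (-0.12, adjusted p = 0.0875) did not pass. T and NK cell genes were higher by 0.15 (28 of 30, adjusted p = 0.00187), with the transcription factor Tbx21 at 0.32 (SE 0.19) and the T-cell receptor chain Cd3e at 0.30 (SE 0.20). Dendritic cell genes were higher by 0.20 (21 of 25, adjusted p = 0.0106) with Bst2 at 0.37 (SE 0.24), and mature B-cell genes by 0.24 (26 of 27, adjusted p = 0.0146) with Cd37 at 0.30 (SE 0.31). Megakaryocyte genes fell by 0.31 (25 of 26 lower, adjusted p = 0.0102), with Thbs1 at -0.62 (SE 0.57). Secondary and tertiary granule genes fell by 0.13 (20 of 23, adjusted p = 0.0123), with the leukotriene hydrolase Lta4h at -0.32 (SE 0.21) and the antimicrobial peptide Camp at -0.10 (SE 0.09). Genes of mitochondrial respiration fell by 0.07 (32 of 36, adjusted p = 0.0106) and skeletal muscle genes fell by 0.22 (17 of 20, adjusted p = 0.0123). MYC targets rose by 0.09 (28 of 38, adjusted p = 0.0024), with the nucleolar proteins Noc4l at 0.25 (SE 0.11) and Ppan at 0.32 (SE 0.14). The alleles pooled as DRAI- lay on opposite sides of WT for megakaryocytes, MYC targets and respiration. Mean megakaryocyte scores were 7.22 in WT, 7.42 in CCAT2-G and 6.40 in CCAT2-T mice. In the same order they were 7.78, 8.01 and 7.74 for MYC targets and 9.79, 9.81 and 9.62 for respiration. Lists were not tested by allele. WNT targets and genes tied to CCAT2 rose by 0.09 (17 of 20, adjusted p = 0.0176), with the WNT antagonist Nkd1 at 0.25 (SE 0.13). Respiration, muscle, MYC targets and WNT targets each had adjusted p = 0.830 with an estimated correlation. In the wider arrays, with the block and within the 5 narrow arrays in turn, the differences were 0.29, 0.18 and 0.05 for T and NK cells, 0.47, 0.23 and -0.05 for dendritic cells, 0.68, 0.35 and -0.04 for mature B cells. They were -0.51, -0.35 and -0.16 for megakaryocytes and -0.17, -0.13 and -0.09 for the granules. In the same order they were -0.09, -0.11 and -0.14 for respiration, -0.67, -0.19 and 0.38 for muscle, 0.17, 0.05 and -0.08 for MYC targets and 0.17, 0.10 and 0.02 for WNT targets. With the block the calls of granules, muscle and MYC targets ended, and within the narrow arrays those of granules and WNT targets. Leaving out WT replicate 4 turned 4 of these lists, to 0.03 for megakaryocytes, -0.09 for mature B cells, 0.11 for muscle and 0.02 for respiration. It ended the calls of T and NK cells (0.04), dendritic cells (0.08) and WNT targets (0.06). Other calls ended without WT replicate 1 (MYC targets, 0.05), WT replicate 3 (mature B cells 0.11, granules -0.07, WNT targets 0.07), CCAT2-G replicate 1 (mature B cells 0.14, respiration -0.04), CCAT2-G replicate 2 (granules -0.07), and CCAT2-G replicate 3 (muscle -0.17). Calls also ended without CCAT2-G replicate 4 (dendritic cells 0.13, mature B cells 0.18, MYC targets 0.03, granules -0.06, WNT targets 0.07). The same held for calls without CCAT2-T replicate 1 (mature B cells 0.18, respiration -0.04), CCAT2-T replicate 2 (respiration -0.04), CCAT2-T replicate 3 (megakaryocytes -0.16, muscle -0.16) and CCAT2-T replicate 4 (megakaryocytes -0.23, muscle -0.17). Values moved without losing the call for mature B cells to 0.49, 0.44 and 0.41 without WT replicates 1 and 2 and CCAT2-G replicate 3. For respiration they moved to -0.13, -0.11 and -0.11 without the same mice. Without WT replicate 1 T and NK cells stood at 0.26, without WT replicate 2 dendritic cells at 0.31, without WT replicate 3 MYC targets at 0.14 and muscle at -0.39. Without CCAT2-G replicate 2 MYC targets stood at 0.06, without CCAT2-G replicate 3 granules at -0.21, without CCAT2-G replicate 4 megakaryocytes at -0.47 and without CCAT2-T replicate 1 muscle at -0.37. With array weights, 3 lists passed in this comparison, mature B-cell (-0.13), muscle (0.03) and respiration genes (0.00665) turned, and the calls of T and NK cells (0.05), WNT targets (0.05), dendritic cells (0.02) and megakaryocytes (-0.02) ended. With the interquartile range as a covariate mature B-cell (-0.05) and respiration genes (0.00825) turned, and the calls of granules (-0.07), megakaryocytes (-0.25), T and NK cells (0.07), dendritic cells (0.11) and WNT targets (0.06) ended. With the mean of a gene's probesets those of dendritic cells (0.16), respiration (-0.05) and WNT targets (0.06) ended. The megakaryocyte call also ended with Xist minus Y-linked genes (-0.13) or the stroma score (-0.02) as a covariate and without the 4 Xist-high arrays (-0.16). The muscle call ended in the last 2 of these settings (-0.15 and -0.16), and the respiration call with the stroma score (-0.05).

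In the same comparison 0 of 14505 genes passed with limma (smallest adjusted p = 0.999), none passed adjusted over the list alone. In total 197 genes had an unadjusted p under 0.05, 144 higher and 53 lower. The smallest p-values among higher genes were those of the haem transporter family member Flvcr2 (0.31, SE 0.09), Ly6g6e (0.26, SE 0.08), the WNT antagonist Sfrp1 (0.34, SE 0.11), Dock4 (0.32, SE 0.10) and Epha1 (0.26, SE 0.08). Among lower genes they were those of Zdhhc15 (-0.39, SE 0.10), the nutrient-sensing GTPase Rragd (-0.67, SE 0.23), Pgap1 (-0.53, SE 0.19), Ttc39b (-0.26, SE 0.10) and Tusc1 (-0.29, SE 0.11). Ezh2 lay at 9.13 ± 0.20 (SD, n = 8) in DRAI- and 9.14 ± 0.18 (SD, n = 4) in WT mice, a difference of -0.01 (SE 0.12), and Myc differed by 0.16 (SE 0.21). Of the lineage markers, Mpo differed by -0.22 (SE 0.23), Csf1r by -0.21 (SE 0.21), Gata1 by -0.23 (SE 0.19), Pf4 by -0.46 (SE 0.70), Cd79a by 0.70 (SE 0.74) and Kit by -0.22 (SE 0.24). The 19 lists that did not pass had mean differences from -0.25 to 0.14, with a smallest adjusted p of 0.0875. The mean differed in sign from the median for 4 of them and from camera's direction for 2. For Dock4, Sfrp1 and Noc4l, 1 probeset pointed the other way.

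The direct comparison of DRAI+ with DRAI- marrow showed its largest shift in mature B-cell and B-cell precursor genes. Of 27 mature B-cell genes 26 were lower in DRAI+ mice, with a mean of -0.99 (camera, adjusted p = 8.35e-16, and adjusted p = 0.661 with an estimated correlation). Of 25 precursor genes 23 were lower, with a mean also of -0.99 (adjusted p = 9.23e-12, and adjusted p = 0.661 with an estimated correlation). No B-cell gene passed over all genes. Adjusted over the list alone, 23 of the mature and 15 of the precursor genes passed. That adjustment leaves out that 31 lists were tested. Genes of a list measured in the same mice are not independent, so these counts are no evidence apart from the shift of the list. Cd79a, a signalling chain of the B-cell receptor, was at 5.77 ± 0.95 (SD, n = 6) in DRAI+ and 8.10 ± 1.34 (SD, n = 8) in DRAI- mice, and its partner Cd79b differed by -1.44 (SE 0.43). Ms4a1 differed by -1.90 (SE 0.55), Ltb by -1.02 (SE 0.27), the survival receptor Tnfrsf13c by -1.35 (SE 0.40) and the inhibitory receptor Cd22 by -1.26 (SE 0.41). The B-lineage factor Pax5 differed by -0.61 (SE 0.17), Cecr2 by -0.85 (SE 0.23) and the surrogate light chain Vpreb1 by -1.46 (SE 0.74). All 6 DRAI+ mice lay below the DRAI- mean of each list. An exact two-sided permutation test of the list scores over 31 lists gave p = 0.0163 for mature B cells (adjusted p = 0.506) and p = 0.0396 for the precursors (adjusted p = 0.568). The difference was -0.74 for mature B cells and -0.75 for the precursors among the 13 wider arrays, and -0.65 and -0.68 with the block. It was -0.78 and -0.83 without the 3 stroma-rich arrays, and -1.31 and -1.18 without the 4 Xist-high arrays. With the interquartile range as a covariate it was -0.71 and -0.72, and 19 mature and 10 precursor genes passed adjusted over the list alone. Among the wider arrays, with the block and without the stroma-rich arrays, 0 genes of either list passed adjusted over the list alone, as did 0 mature B-cell genes without CCAT2-GT replicate 4, where the mean was -0.85. The precursor count was 4 without CCAT2-G replicate 1 or 4 or CCAT2-GT replicate 2 or 6, and CCAT2-G replicate 3 had the lowest DRAI- score of that list, 5.53.

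Monocyte, granulocyte-monocyte precursor and megakaryocyte genes rose as groups in DRAI+ against DRAI- marrow, while mature neutrophils (0.22, adjusted p = 0.0641), their secondary and tertiary granules (0.05, adjusted p = 0.378) and eosinophils, basophils and mast cells (0.34, adjusted p = 0.0511) did not pass. Monocyte and macrophage genes rose by 0.38 (29 of 31 higher, adjusted p = 8.27e-06, and adjusted p = 0.661 with an estimated correlation). Of these, 1 passed adjusted over the list alone. Clec4a3 was higher by 1.05 (SE 0.28), Csf1r, the receptor for the growth factor CSF-1, by 0.53 (SE 0.18), the pore-forming protein Mpeg1 by 0.44 (SE 0.16) and the macrophage antigen Adgre1 by 0.77 (SE 0.30). Granulocyte-monocyte precursor genes rose by 0.24 (17 of 20, adjusted p = 0.000496, and adjusted p = 0.733 with an estimated correlation), with Nkg7 at 0.58 (SE 0.17), the peroxidase Mpo at 0.46 (SE 0.21) and Cst7 at 0.43 (SE 0.21). Megakaryocyte and platelet genes rose by 0.74 (26 of 26 higher, adjusted p = 2.09e-07, and adjusted p = 0.834 with an estimated correlation). Examples are Thbs1 at 1.57 (SE 0.50), Selp at 1.19 (SE 0.48), the ATP receptor P2rx1 at 0.90 (SE 0.36) and the transcription factor Fli1 at 0.33 (SE 0.15), though only 3 of 6 DRAI+ mice lay above the DRAI- mean. By allele, mean megakaryocyte scores were 7.65 in DRAI+, 7.42 in CCAT2-G and 6.40 in CCAT2-T mice. Without the 3 stroma-rich arrays the megakaryocyte list turned to -0.19, and without CCAT2-GT replicate 4 or 6 it differed by 0.35 or 0.39. The monocyte list differed by 0.11 without the stroma-rich arrays and by 0.20 without CCAT2-GT replicate 6. Among the wider arrays and with the block, the differences were 0.25 and 0.26 for monocytes, 0.66 and 0.61 for megakaryocytes and 0.08 and 0.10 for the precursors, whose call ended in the first of them. With array weights monocytes stood at 0.25 and megakaryocytes at 0.33, and without the 4 Xist-high arrays megakaryocytes stood at 1.27 and the precursors at 0.38. With the stroma score as a covariate megakaryocytes stood at 0.46.

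Stress, interferon and respiration genes also rose in DRAI+ against DRAI- mice. Genes of the unfolded protein and integrated stress response were higher by 0.25 (27 of 30, adjusted p = 8.27e-06, and adjusted p = 0.661 with an estimated correlation), with Edem1 at 0.60 (SE 0.17), the chaperone Dnajc3 at 0.49 (SE 0.15) and Xbp1 at 0.44 (SE 0.14). All 6 DRAI+ mice lay above the DRAI- mean. Edem1 and Xbp1 are also on the plasma cell list, which differed by 0.14 without passing (camera, adjusted p = 0.0505). The shifts of these lists were not told apart. Interferon genes were higher by 0.21 (32 of 39, adjusted p = 6.84e-05, and adjusted p = 0.885 with an estimated correlation), with Ifi204 at 0.74 (SE 0.22), Slfn5 at 0.66 (SE 0.25) and the GTPases Gbp2 and Irgm1 at 0.53 (SE 0.20) and 0.37 (SE 0.15). Respiration genes were higher by 0.13 (32 of 36, adjusted p = 5.51e-05, and adjusted p = 0.913 with an estimated correlation), with the ATP synthase subunits Atp5b and Atp5a1 at 0.35 (SE 0.15) and 0.35 (SE 0.16). T and NK cell genes fell by 0.16 (23 of 30 lower, adjusted p = 0.0445, and adjusted p = 0.923 with an estimated correlation), with the interleukin receptor chain Il2rb at -0.76 (SE 0.23), the adhesion molecule Cd2 at -0.77 (SE 0.32) and Nkg7 opposite to the list. Among the wider arrays and with the block the differences were 0.10 and 0.12 for the stress response, 0.13 and 0.21 for interferon, 0.01 and 0.01 for respiration and -0.09 and -0.06 for T and NK cells. The calls of respiration and of T and NK cells ended in both, that of the stress response in the first. Without CCAT2-GT replicate 2 the stress list differed by 0.14. Without CCAT2-GT replicate 3 the interferon call ended (0.10), which was 0.12 without replicate 4 and 0.33 without replicate 6. Respiration differed by 0.08 without CCAT2-GT replicate 6. The T and NK cell call ended without CCAT2-G replicate 1 (-0.13), CCAT2-T replicate 2 or 3 (-0.14 each) and CCAT2-GT replicate 1 (-0.14), 2 (-0.08) or 4 (-0.08). The value was -0.29 without CCAT2-GT replicate 3. That call also ended with array weights (-0.07), without the 3 stroma-rich arrays (-0.07), with the interquartile range as a covariate (-0.08), with quantile normalization (-0.17) and with no filter on dim probes (-0.16). The interferon call ended with Xist minus Y-linked genes as a covariate (0.10), and the value was 0.35 with array weights. Respiration differed by 0.07 without the stroma-rich arrays, and T and NK cells by -0.29 without the Xist-high ones.

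Across DRAI+ and DRAI- mice 0 of 14505 genes passed with limma (smallest adjusted p = 0.456). Of them, 1388 had an unadjusted p under 0.05, 557 higher and 831 lower, against 725 by chance. In splits of the same mice, the real one included, 14 of 100 gave as many, with a median of 498 in the others. Chance can thus not be excluded for this count. Adjusted over the list alone, 50 list members passed, summed over the lists. Besides the counts of the B-cell and monocyte lists these included 6 of the dendritic cell list (mean -0.32, adjusted p = 0.0505), 4 of the plasma cell list (0.14, adjusted p = 0.0505) and 1 of DNA repair (-0.05, adjusted p = 0.447). The dendritic cell list shares 2 genes with the B-cell precursors and 1 with mature B cells, so a gene can be counted more than once. Camera called 6 lists higher and 3 lower, and with quantile normalization 9 and 2. The smallest p-values belonged to Zkscan5 (0.42, SE 0.10), the dehydrogenase Aldh7a1 (0.49, SE 0.12), the macrophage growth factor Csf1 (0.35, SE 0.09), Clec4a3 and the phospholipase Pla2g7 (1.01, SE 0.27) among higher genes. Among lower ones they belonged to the retinoic acid-binding protein Crabp2 (-0.48, SE 0.09), the co-chaperone Dnajc7 (-1.02, SE 0.21), Serinc5 (-0.75, SE 0.17), Igf1os (-0.47, SE 0.11) and the endosomal GTPase Rab5b (-0.47, SE 0.11). Without CCAT2-G replicate 3, 7 genes passed, namely Pla2g7, Serinc5, Dnajc7, 4930426D05Rik, Mctp1, Abcd2 and Hdac9. Those not listed before were named after their values were seen. Ezh2 lay at 8.96 ± 0.17 (SD, n = 6) in DRAI+ against 9.13 ± 0.20 (SD, n = 8) in DRAI- mice, a difference of -0.17 (SE 0.11), and Myc differed by 0.05 (SE 0.18). Lineage markers outside the B cells had differences of 0.07 for Elane (SE 0.29), 0.10 for Ltf (SE 0.17), 0.23 for Gata1 (SE 0.17), -0.14 for Klf1 (SE 0.20), 0.58 for Pf4 (SE 0.62), -0.30 for Cd3e (SE 0.17) and 0.28 for Kit (SE 0.21). For Zkscan5, Aldh7a1 and Csf1, 1 probeset pointed the other way. The 22 lists that did not pass had means of -0.32 to 0.34. Among them the mean differed in sign from the median for 1 and from camera's direction for 2.

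**Figure D2:**
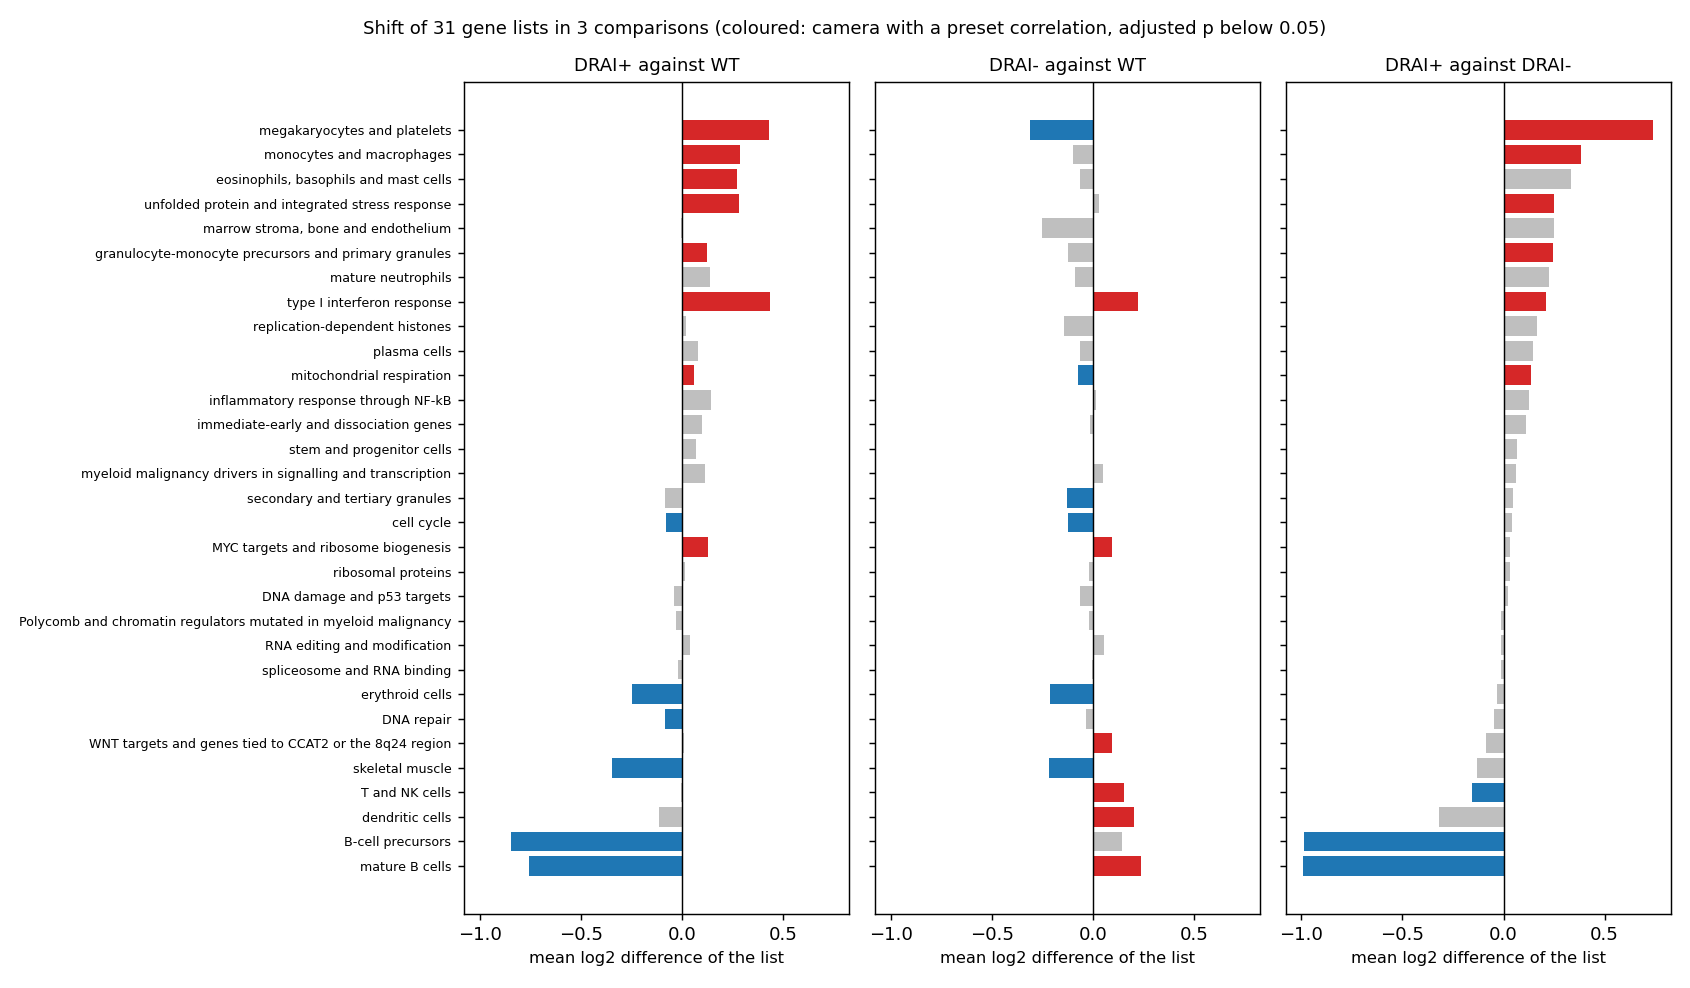
Mean log2 difference of the measured genes of each of the 31 lists in the 3 comparisons, as bars from 0, coloured where camera's adjusted p with its preset correlation was below 0.05 (red higher, blue lower). Mature B-cell genes lie at -0.76 in DRAI+ against WT, 0.24 in DRAI- against WT and -0.99 in DRAI+ against DRAI-, and no list passed with an estimated correlation.

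The alleles were compared through the 4 CCAT2-G and 4 CCAT2-T mice. Add1, which encodes the cytoskeletal protein alpha-adducin, had the smallest p between them, at 8.69 ± 0.24 (SD, n = 4) in CCAT2-G and 9.73 ± 0.27 (SD, n = 4) in CCAT2-T mice, a difference of -1.04 (SE 0.16, limma adjusted p = 0.0579) that did not pass. All 3 of its probesets differed in the same direction, and it was higher in CCAT2-T than in WT mice by 0.67 (SE 0.16). It passed with quantile normalization (adjusted p = 0.0254), with the stricter filter (adjusted p = 0.0476) and without CCAT2-T replicate 1 (adjusted p = 0.0403). The DNA damage adaptor Trp53bp1 (-0.73, SE 0.16) and Gapvd1 (-0.43, SE 0.11) were the next lower genes in CCAT2-G. The mitochondrial RNase P subunit Trmt10c (0.71, SE 0.17), the interleukin-1 receptor accessory protein Il1rap (0.65, SE 0.16) and the mitochondrial ribosomal protein Mrps24 (0.71, SE 0.18) were the higher ones, with 4 of 5 probesets in the same direction for Gapvd1. With limma 0 genes passed between the alleles and 912 had an unadjusted p under 0.05, 611 higher and 301 lower in CCAT2-G.

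Each allele was also set against WT. In CCAT2-G mice Il1rap was higher by 0.61 (SE 0.16), the cytokine signalling inhibitor Socs3 by 1.52 (SE 0.42) and Igfbp6 by 0.79 (SE 0.22), while Zfp697 (-0.39, SE 0.12), the beta-glucan receptor Clec7a (-0.89, SE 0.27) and Gapvd1 (-0.35, SE 0.11) were lower. In CCAT2-T mice Add1, Slc25a48 (0.42, SE 0.11) and Wiz (0.45, SE 0.12) were higher, and the exoribonuclease Xrn2 (-0.61, SE 0.14), Zdhhc15 (-0.46, SE 0.11) and the ubiquitin ligase Nedd4 (-0.44, SE 0.12) were lower. None of these passed with limma, which called 0 genes in either comparison (smallest adjusted p = 1.00 for CCAT2-G and 0.928 for CCAT2-T). Unadjusted p was under 0.05 for 228 genes in CCAT2-G and 451 in CCAT2-T.

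**Figure D3:**
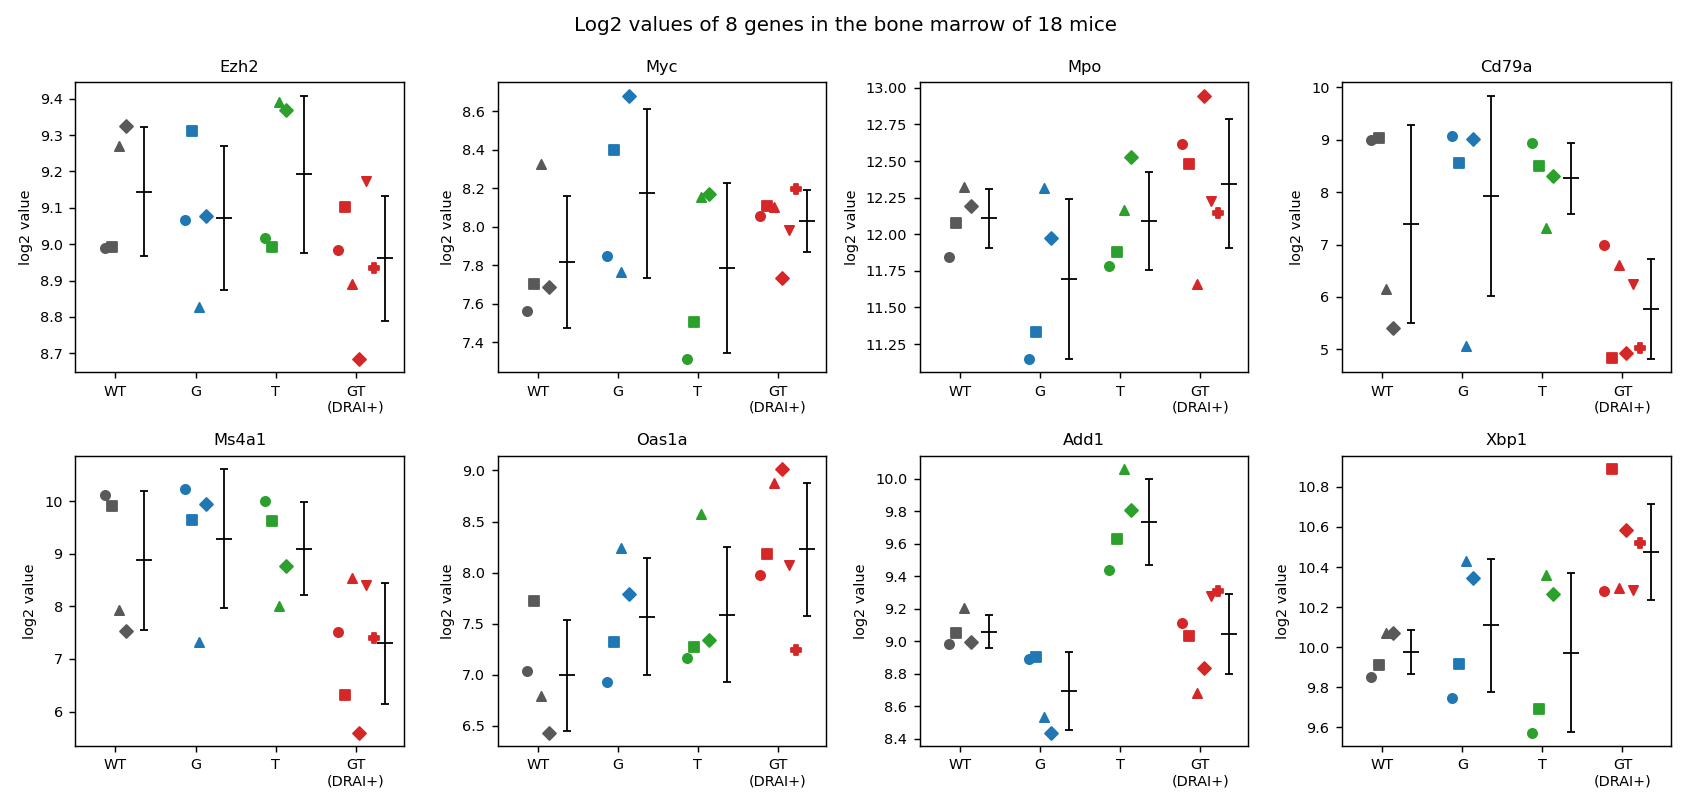
Log2 expression of 8 genes (Ezh2, Myc, Mpo, Cd79a, Ms4a1, Oas1a, Add1 and Xbp1) in each mouse, by group, with 1 point per mouse and a bar for the mean ± SD. Cd79a averages 5.77 in the 6 CCAT2-GT mice, and the 4 CCAT2-T mice lie above the 4 CCAT2-G mice for Add1.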

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

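All tests of explanations in this part, and the count of other splits, had their predictions written after the results were seen, while the search for mice that stand apart within their group followed a fixed rule. For the sexes and the narrow arrays the bar was reset after their values were known, from an interval wholly beyond a set part of the difference to one wholly below 0, and under the earlier bar unequal sexes stayed open too. That rule looks for a highest or lowest mouse far from the nearest of its group, and chance gives about 1 such mouse in 20 groups. It found such a mouse in 13 of 93 groups of list scores (7 different mice), where chance gives 4.65, and in 9 of 183 groups of named genes (6 different mice), where chance gives 9.15.

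WT replicate 3 stood above the other WT mice for immediate-early and dissociation genes (8.94, others 6.71 to 7.02), mature neutrophils (9.74, others 8.69 to 8.86), DNA damage and p53 targets (6.88, others 6.51 to 6.54), replication-dependent histones (6.35, others 5.20 to 5.39) and the gene Socs3 (6.96, others 4.89 to 5.20). WT replicate 4 stood above them for megakaryocytes and platelets (8.23, others 6.78 to 6.96), Ly6g6e (4.57, others 4.43 to 4.44) and Rragd (6.87, others 5.89 to 6.05). Among the 8 DRAI- mice, CCAT2-G replicate 3 was lowest for B-cell precursors (5.53, others 6.87 to 7.92), Cd79a (5.07, others 7.32 to 9.08) and Serinc5 (6.55, others 7.26 to 7.75) and highest for eosinophils, basophils and mast cells (6.44, others 5.16 to 5.71) and Pla2g7 (9.46, others 7.13 to 7.82). CCAT2-G replicate 4 was highest for stem and progenitor cells (7.69, others 7.17 to 7.41), and CCAT2-T replicate 1 for skeletal muscle (6.05, others 4.61 to 5.01) and Dock4 (4.37, others 3.91 to 4.10). Among the 6 DRAI+ mice, CCAT2-GT replicate 2 was highest for the unfolded protein response (8.42, others 7.67 to 7.83), RNA editing and modification (6.77, others 6.70 to 6.73) and Il1rap (6.55, others 5.79 to 6.03) and lowest for myeloid malignancy drivers (7.28, others 7.41 to 7.49). CCAT2-GT replicate 6 was lowest for Polycomb and chromatin regulators (7.67, others 7.74 to 7.77) and Ltf (12.3, others 13.0 to 13.4).

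The 52 genes of both B-cell lists, joined after their shifts were seen, were lower in DRAI+ than in DRAI- mice by -0.99 (95% interval -1.79 to -0.19, unadjusted exact permutation p = 0.0236, while over 31 lists the adjusted p was 0.506 for mature B cells and 0.568 for the precursors). Dilution by stroma and megakaryocytes was assumed to lower erythroid and granule genes as much, but these differed by -0.032 (interval -0.40 to 0.34) and 0.046 (interval -0.40 to 0.49). Under that assumption, which was not tested, the values argue against dilution as the whole cause. Without the 3 stroma-rich arrays, however, the B-cell difference was -0.80 (interval -1.77 to 0.17, 4 against 8 mice). That interval includes 0, so this check leaves dilution open. Without the 4 Xist-high mice the difference was -1.25 (interval -2.27 to -0.23, 3 against 7 mice), and with Xist minus Y-linked genes as a covariate the mature and precursor lists stood at -1.03 and -0.98, which argues against unequal sexes as the whole cause, though a part stays open. The 5 narrow arrays, none DRAI+, cannot be told apart from the DRAI status as the whole cause, since without them the difference was -0.75 (interval -1.73 to 0.24, 6 against 5 mice), which includes 0, although with the interquartile range as a covariate it was -0.74 (interval -1.44 to -0.041), which argues only against a linear trend with the spread as the whole cause. A smaller B-cell share tied to the DRAI+ status remains a hypothesis, which the narrow and the stroma-rich arrays leave open.

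The list of marrow stroma, bone and endothelium differed between mice of the same group, from 5.09 to 6.93 in WT and from 4.61 to 7.68 in CCAT2-GT mice. A candidate explanation is that bone-lining tissue was recovered with the marrow of some mice, which would bring stroma and megakaryocyte genes together. Over the 18 mice the 2 lists had Pearson's r = 0.888 (permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 2e-05) and Spearman's rho = 0.833 (permutation p = 3e-05, adjusted p = 6e-05), r = 0.829 without the 2 farthest mice and 0.899 for deviations from the group means. Whether skeletal muscle was carried over stays open. Over the same mice the stroma and muscle lists had r = 0.458 (permutation p = 0.0554), with an interval of -0.01 to 0.76 that includes 0. That r was 0.549 without the 2 farthest mice and 0.554 for deviations from the group means. Their ranks did correlate, with rho = 0.692 (permutation p = 0.00206, adjusted p = 0.00206). The rule for this explanation used Pearson's r alone and did not decide it. These 2 relations were the only ones computed, and no biological explanation was tested.

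Splits of the same mice into groups of the same sizes, the real one included, were fitted to see whether chance can be excluded for the counts. For genes past the threshold the real count is 0 in each comparison, so all splits give as many by construction (100 of 100 for the comparisons by DRAI status and 35 of 35 for those of the alleles) and say nothing about chance. The highest other count was 529 in DRAI+ against WT, 2750 in DRAI- against WT, 264 in DRAI+ against DRAI-, 391 in CCAT2-G against WT, 2430 in CCAT2-T against WT and 544 in CCAT2-G against CCAT2-T. Chance cannot be excluded for the counts at an unadjusted p under 0.05 or for the gene lists. At that p, as many were found in 55 of 100 splits for DRAI+ against WT (real 382, highest other 3055), 80 of 100 for DRAI- against WT (197 and 5354), 14 of 100 for DRAI+ against DRAI- (1388 and 3822), 26 of 35 for CCAT2-G against WT (228 and 4245), 15 of 35 for CCAT2-T against WT (451 and 5318) and 10 of 35 for CCAT2-G against CCAT2-T (912 and 4142). For gene lists, 63 of 100 splits gave as many in DRAI+ against WT (14, highest other 25), 65 of 100 in DRAI- against WT (12 and 21) and 95 of 100 in DRAI+ against DRAI- (9 and 23). For these 3 comparisons in turn, camera called a median of 15, 14 and 13 lists in the other splits, above each real count. The median of the other splits was 0 genes in each comparison, and in the order above only 4, 3 and 5 of 100 and 2, 1 and 2 of 35 splits called any gene. The highest of these, at 264 genes or more where the real one calls 0, point to a structure of the samples. The split of 2430 genes set WT replicates 1 and 2 and CCAT2-T replicates 1 and 2, all narrow arrays, against the other 4 mice. Those included WT replicate 3 and CCAT2-T replicates 3 and 4, with immediate-early scores of 8.94, 9.01 and 8.01, and the stroma-rich WT replicate 4. These differences cannot be told apart in that split. All 5 narrow arrays lay on the same side in the split of 2750. Both real comparisons called 0 genes with the narrow arrays as a block, as they did without it. The splits were not refitted with the block, so this says nothing about their structure. In the split of 529 the 3 stroma-rich mice lay on the same side.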

How the results depend on the processing

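The settings that leave out stroma-rich, narrow or Xist-high arrays, that use the interquartile range, stroma or immediate-early score as a covariate, that treat the narrow arrays as a block or stay within them, and the permutation of list scores were chosen after seeing the data; the others were planned. Of named-gene results, 4308 kept their direction and side of the threshold under alternatives and 2569 with 1 mouse left out, 127 and 67 changed sign without passing either way, and 25 and 4 newly passed. None had a call to lose. Of list results, 1657 and 857 kept both, 133 and 99 changed sign without passing either way, 106 and 97 newly passed, 168 and 51 lost the call, and 41 and 12 changed sign with a call on at least 1 side. Low signal limits dim genes, since 14505 of 18194 genes lay above the filter at 3.30. The cause of the changes below was not tested, except that fewer mice or genes enter some fits.

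With an estimated correlation, with fry and with the exact permutation of list scores, 0 lists passed in DRAI+ against WT, 0 in DRAI- against WT and 0 in DRAI+ against DRAI-. With every probeset tested, 2 passed in DRAI+ against DRAI-. Quantile normalization called 1 gene and the filter at the 50th percentile 1 gene in CCAT2-G against CCAT2-T, Add1 in both. Array weights called 456 genes in DRAI+ against WT, where the cell cycle turned to 0.064. They called 3 lists in DRAI- against WT, with mature B cells at -0.13, muscle 0.026, cell cycle 0.045, respiration 0.00665, spliceosome 0.058 and interferon -0.022. With Xist minus Y-linked genes as a covariate, stroma stood at 0.49 and immediate-early genes at -0.33 in DRAI+ against WT.

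Without the 3 stroma-rich arrays, megakaryocytes stood at -0.16 and the cell cycle at 0.026 in DRAI+ against WT. In DRAI- against WT 5 lists passed, with megakaryocytes at 0.026, mature B cells -0.095, muscle 0.11 and respiration 0.022, and in DRAI+ against DRAI- 14 passed, with megakaryocytes at -0.19 and stroma -0.42. Without the 5 narrow arrays, granulocyte-monocyte precursors stood at -0.00549, T and NK cells 0.20, ribosomal proteins -0.078 and respiration -0.083 in DRAI+ against WT, and erythroid cells at 0.10, MYC targets -0.11 and ribosomal proteins -0.057 in DRAI+ against DRAI-. Without the 4 Xist-high arrays, stroma stood at 0.44 in DRAI+ against WT and 15 lists passed in DRAI+ against DRAI-. With the interquartile range as a covariate, mature B cells stood at -0.053, respiration at 0.00825 and the spliceosome at 0.067 in DRAI- against WT. With the stroma score as a covariate 14 lists passed in DRAI+ against DRAI-.

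With the narrow arrays as a block, granulocyte-monocyte precursors stood at -0.067, T and NK cells 0.12, MYC targets -0.026, ribosomal proteins -0.097 and respiration -0.10 in DRAI+ against WT. In DRAI+ against DRAI- 15 lists passed, with MYC targets at -0.080 and ribosomal proteins -0.049. Within the narrow arrays, in DRAI- against WT, erythroid cells stood at 0.060, mature B cells -0.038, dendritic cells -0.054, muscle 0.38, MYC targets -0.082 and interferon -0.10.

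With 1 mouse left out, list values in DRAI+ against WT ranged from -0.13 to 0.10 for T and NK cells, -0.34 to 0.32 for stroma and -0.15 to 0.031 for the cell cycle. In DRAI- against WT 5 lists (without WT replicate 4) to 19 (without WT replicate 3) passed, and values ranged from -0.20 to 0.15 for neutrophils, -0.47 to 0.026 for megakaryocytes, -0.095 to 0.49 for mature B cells, -0.39 to 0.11 for muscle, -0.13 to 0.022 for respiration, -0.059 to 0.062 for the spliceosome and -0.25 to 0.49 for immediate-early genes. In DRAI+ against DRAI- 0 to 7 genes and 10 (without CCAT2-GT replicate 4) to 14 lists (without CCAT2-G replicate 3) passed, and in CCAT2-G against CCAT2-T 0 to 1 genes.

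The replicate numbers were not taken as pairs, since the labels tie them to no shared animal, litter or day and not every same-numbered pair correlated above 0.1. A shared batch could miss that bar too. Deviations of the 24 such pairs correlated at -0.36 to 0.67 (median 0.0861, 11 over 0.1), those of the 96 pairs of other numbers had a median of -0.067, and 6 of 16 arrays correlated best with their own number. All 5 narrow arrays carry number 1 or 2, so the numbers are not free of the differences between arrays. With the replicate block 0 genes passed in every comparison, and 15, 13 and 11 lists in DRAI+ against WT, DRAI- against WT and DRAI+ against DRAI-.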

Other observations

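The values in this part were chosen after seeing the data, and they carry no explanation. Immediate-early and dissociation genes, which cells switch on within minutes of handling or stimulation, had scores of 8.94 in WT replicate 3, 9.01 and 8.01 in CCAT2-T replicates 3 and 4 and 8.70 and 8.39 in CCAT2-GT replicates 1 and 5, and 6.71 to 7.49 in the other 13 mice. The high mice lie in 3 of the 4 groups. Add1, the gene of smallest p between the alleles, stood at 9.11, 9.03 and 8.68 in CCAT2-GT replicates 1 to 3, whose mouse identifiers carry the letter G, and at 8.84, 9.28 and 9.31 in replicates 4 to 6, whose identifiers carry the letter T, against a WT mean of 9.06 ± 0.10 (SD, n = 4).

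Whether the difference between DRAI+ and DRAI- mice depends on the identifier letter was tested as an interaction with limma, which called 0 genes (smallest adjusted p = 0.700, 1006 genes at an unadjusted p under 0.05). Of the 31 list scores, 0 passed an exact permutation test after adjustment and 1 did before it. That was the megakaryocyte and platelet list, at -0.65 for DRAI+ minus DRAI- in letter G and 2.13 in letter T, a difference of 2.78 (exact permutation p = 0.0329, adjusted p = 0.695). Among DRAI- mice the letter is the allele, so this value includes the difference between CCAT2-G (mean 7.42) and CCAT2-T mice (mean 6.40). Of the 3 DRAI+ mice of letter T, CCAT2-GT replicates 4 and 6, both stroma-rich, had scores of 9.61 and 9.38 and replicate 5 had 6.58, and the stroma list differed by -0.63 in letter G and 1.13 in letter T. When every probeset was tested, the 2 that passed in DRAI+ against DRAI- were higher by 2.37 and 2.81 (limma adjusted p = 0.00764 each), and the platform annotation used here lists no gene for either.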
